A study of Mus musculus with 15 samples.

How the data were processed

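RNA sequencing was analysed for 15 libraries of primary mouse lung fibroblasts, cells grown out of lung tissue, from wild-type BALB/cJ mice. Per the labels, the cultures were left untreated or were given cytokines for 20 h. The 5 groups of 3 libraries were untreated, IL-33, IL-33 with IL-17A, IL-33 with IL-13, and IL-33 with both IL-13 and IL-17A, called the triple combination. IL-33 is an alarmin of the IL-1 family released by damaged barrier cells, IL-13 is a type 2 cytokine that signals through STAT6, and IL-17A is a cytokine of type 3 immunity. Total RNA was isolated with a Qiagen RNeasy kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The labels give no replicate numbers, culture dates or animals. Replicates were numbered in accession order, which does not pair them across groups. P-values measure only the spread between these libraries, which may be technical.

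The deposited values are TPM, a length-scaled measure of transcripts, for 18078 Ensembl genes per library, and each library has the same total. TPM divides reads by a length and scales each library to a fixed total. A rise of a few abundant transcripts thus lowers the values of all others, and total RNA per cell is not measured. The length used here appears to be the span of the gene from start to end, introns included. Levels of different genes, and the filter at 1 TPM used here, then depend on intron length too. The submitters' processing notes name the aligner HISAT2, without a version, and the mouse genome build mm10. Ensembl gene models were used per the file headers. The tool that turned alignments into TPM, its handling of reads that match several genes, its use of strand and its filter on low values are not given in the sources used here. Gene symbols and coordinates were taken from the files. Of the 18078 gene identifiers, 18062 were found in GENCODE vM21, an annotation of the same build, and 17882 had the same start and end there. The files hold 14972 protein-coding genes and 898 processed pseudogenes, and 19 symbols are shared by several identifiers (40 identifiers). Because strand and multi-mapping rules are not known, values of genes with near-identical copies are uncertain, which concerns Serpina3g, Ifit3, Rnase2a, Pilrb2, the histone genes H2ac13 and H2bc15, the class I genes H2-K1, H2-D1 and H2-Q4, and the pair Hspa1a and Hspa1b.

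TPM carries no depth, so depth was estimated from the smallest steps between low values of genes with a single annotated transcript. By this estimate 1 read on a 1-kb transcript was worth 0.730 to 1.13 TPM and 3 reads 2.19 to 3.40 TPM. Only 54.9% to 57.1% of the checked low values of the libraries, 1986 to 2138 values each, were whole reads within a tolerance of 0.03. This check used transcript length. The lowest values above 0 of Csf2 (0.473 TPM, untreated replicate 2) and Csf3 (0.420 TPM, untreated replicate 1) match 1 read over the whole gene span. There 1 read on 1 kb was worth 1.13 and 0.993 TPM. The low share of whole reads thus does not show that reads cannot be recovered. Reads over gene span were not computed, and no comparison of groups was tested on reads. Values under about 3 TPM therefore rest on very few reads in genes that span about 1 kb, and on more reads in longer genes.

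The comparisons, the tests, the 31 gene lists and the rule for naming genes were fixed before the data were examined. The test written first was one for counts, with limma on log2 values as its written replacement in case the files held normalized values. The files hold TPM, so limma (version 3.58.1, R 4.3.3) was fitted with its trend and robust options to log2(TPM + 1). All 15 libraries entered 1 fit with a mean per group, and genes at 1 TPM or more in at least 3 libraries were tested. This kept 13887 genes and left out 4191. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of each comparison, and a gene was called at an adjusted p under 0.05. All log2 changes are on the log2(TPM + 1) scale, which understates the change of low genes. The 9 comparisons were each cytokine condition against untreated, IL-17A or IL-13 added to IL-33, each of them added to the other combination, and the interaction of IL-13 and IL-17A in the presence of IL-33. Files were read and joined with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

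The lists hold 434 genes, of which 395 are in the files. They cover the receptors of the 3 cytokines, secreted factors that act on macrophages, chemokines, response genes of IL-17, STAT6, NF-kB and interferon, antigen presentation, matrix, contractile genes, proteases, eicosanoid enzymes, complement, cell cycle, metabolism, stress responses, growth factors, mitochondrially encoded genes, and markers of fibroblasts and of other lung cells. The 28 lists with at least 3 tested members were tested with camera, which asks whether a list moves relative to other genes, with a preset correlation of 0.01 between genes, and again with a correlation estimated for each list. The rotation test fry, which asks whether the members on balance move one way, was run beside it. List p-values were adjusted over the 28 lists of a comparison. Members were also counted with adjustment over the list alone.

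Genes are named by the fixed rule. For IL-33 against untreated, IL-17A added to IL-33, IL-13 added to IL-33 and the triple combination against untreated it takes the 10 called genes with the largest rise and the 10 with the largest fall, and the first 5 of each direction elsewhere. Their ranges must not overlap between groups and the higher group must reach 5 units, written as CPM before the data were examined and applied to TPM. Unnamed, Gm and Rik genes are skipped. It adds up to 4 members of each list with the smallest adjusted p, the receptors, and Csf1, Csf2, Csf3, Ccl2, Ccl7, Ccl11, Il6, Cxcl1, Col1a1 and Acta2.

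The limma step was tested on data simulated for all 15 libraries from the mean level of each gene. In IL-33 against untreated 14385 genes were tested, and 200 genes had been changed in the IL-33 libraries. It recovered 14.9% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 97.0% of those changed 4-fold. Of its 121 calls 10 were false (8.26%). The simulation gave all genes the same extra spread beyond counting and held no library set, so these rates do not cover such a set. It also drew reads by transcript length and not by gene span. Genes with introns thus had fewer simulated reads than the deposited values carry, and these rates do not describe their depth.

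Replicates were compared on estimated reads of 1940 genes with a single annotated transcript. The values of these genes were whole reads within the tolerance in every library, or too high to tell. As transcript length was used, reads of genes with introns that were too high to tell are underestimated. Untreated replicates 1 and 2 were closest, with a chi-square per degree of freedom of 1.09 over 719 genes (p = 0.0521) and 5 genes that differed by exact tests after Benjamini-Hochberg adjustment. These p-values cover counting error only. They cannot tell a technical replicate from a separate culture. Untreated replicates 1 and 2 were kept separate, and averaging them was run as an alternative. Other pairs came near. The chi-square per degree of freedom was 1.165 for replicates 2 and 3 of the triple combination, with 3 genes that differed. It was 1.18 for replicates 1 and 2 with IL-33 and IL-13, with 5 such genes. These pairs were not averaged. The alternatives written before the data were examined were a pseudocount of 0.1, no filter, a fit of the compared groups alone, leaving out each library in turn, the estimated correlation and all genes for the agreement of effects. A second count test and other size factors, also written then, need counts and were not run. After the data were seen, 8 alternatives were added, among them a term for a set of 6 libraries that differ from the other 9, each set alone, median-ratio scaling of TPM (factors 0.949 to 1.09) and removal of each library's trend with GC content (lowess span 0.3). GC content was known for 99.9% of the genes.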

Results

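The series asks what IL-33, alone or with IL-17A or IL-13, does to fibroblasts of the lung, and which secreted factors acting on macrophages these cells express. RNA was measured in 15 libraries of primary mouse lung fibroblasts, 3 untreated and 3 for each of IL-33, IL-33 with IL-17A, IL-33 with IL-13, and the triple combination, all after 20 h. Each library has between 12854 and 13159 genes at 1 TPM or more. The cultures expressed fibroblast genes in all libraries. The most abundant fibroblast marker, the collagen gene Col1a1, averaged 4658 TPM, and the 14 fibroblast markers had a median of 175 TPM. Macrophage transcripts were abundant too: Lyz2, the lysozyme gene of myeloid cells (chromosome 10, 117277331 to 117282321), averaged 9362 TPM with a range of 8628 to 10467. Of the macrophage markers, 13 of the 14 in the files averaged 10 TPM or more, with a list median of 302 TPM. The median of the epithelial markers was 0.473 TPM, of endothelial markers 0.225, of lymphocyte and ILC2 markers 1.80 (highest member Thy1, also a fibroblast gene, 800 TPM), of neutrophil and eosinophil markers 4.88 (highest member S100a8, 80.4 TPM), of mast cell and basophil markers 7.46 (highest member Mcpt8, 122 TPM), of smooth muscle and pericyte markers 8.998 and of mesothelial markers 3.59 TPM.

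The libraries did not differ by treatment alone. In 6 of them, all 3 with IL-33 and IL-13, replicates 2 and 3 with IL-33 and IL-17A and replicate 1 of the triple combination, the 13 mitochondrially encoded genes made up 3.69% to 4.09% of TPM, against 5.02% to 6.40% in the other 9. Ribosomal protein genes made up 7.84% to 8.08% in these 6 and 7.24% to 7.71% in the others. This set is not a group of the study. It was seen in the data, and its 6 libraries are consecutive in accession order. A term for it in the fit was called for 2262 genes, 623 higher and 1639 lower inside the set. As each group has its own mean, the term rests on the 2 groups with libraries of both kinds. These are IL-33 with IL-17A (1 outside, 2 inside) and the triple combination (2 outside, 1 inside). For comparisons that contain libraries of the set the number of all called genes with the term is given too, and for some lists the count of members. The labels name no batch, and untreated and IL-33 libraries are all outside the set while those with IL-33 and IL-13 are all inside, so values within each part exist only for some comparisons.

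**Figure D1:**
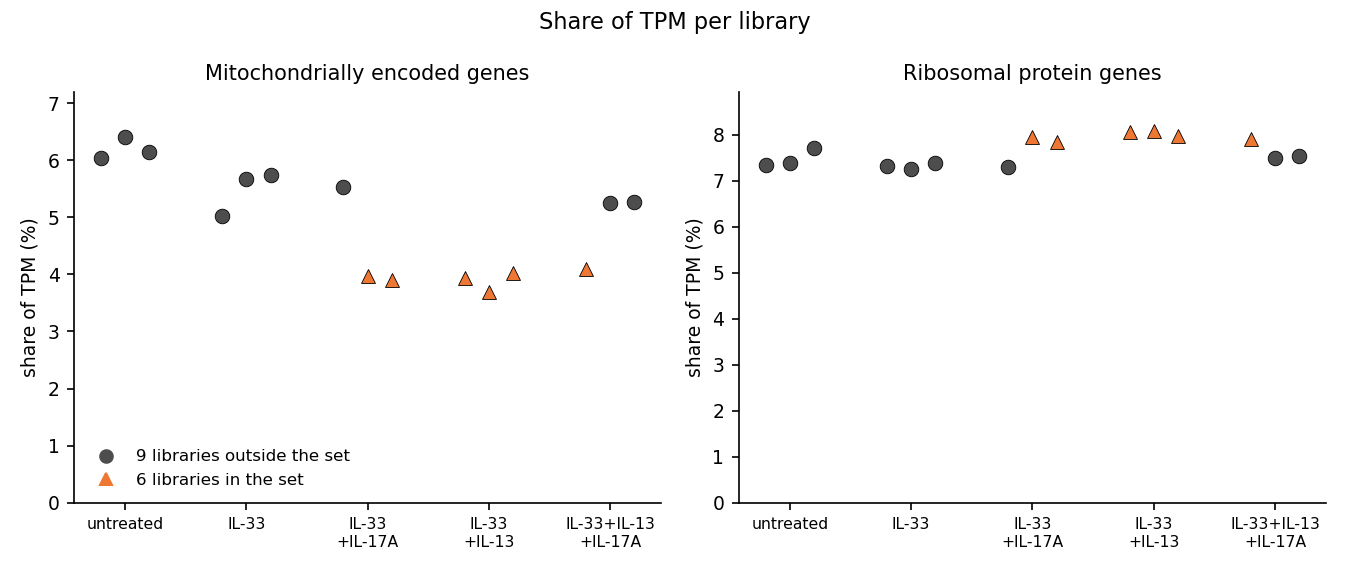
Share of TPM (%) from mitochondrially encoded genes and from ribosomal protein genes in each of the 15 libraries, by group; circles are the 9 libraries outside the set and triangles the 6 inside it. The 6 triangles lie at 3.69% to 4.09% for mitochondrial genes, below all circles at 5.02% to 6.40%.

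IL-33 alone was compared with untreated cells first. Neutrophil chemokines and growth factors were among the largest rises. Lcn2, which encodes the iron-scavenging protein lipocalin 2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), went from 0.398 ± 0.198 to 273.8 ± 10.8 TPM (SD, n = 3), a log2 change of 7.63 ± 0.10 (SE, limma adjusted p = 9.7e-14). The neutrophil chemokine genes Cxcl1 (chromosome 5, 90891241 to 90893115) and Cxcl5 (chromosome 5, 90759360 to 90761624) rose from 9.14 ± 2.68 to 1103 ± 73.6 TPM and from 24.0 ± 2.25 to 2049 ± 157 TPM, log2 changes of 6.80 ± 0.15 and 6.36 ± 0.07. Csf3, the gene of the granulocyte growth factor G-CSF (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629), rose by 3.86 ± 0.13 on the log2 scale (adjusted p = 5.5e-10) from 0.140 ± 0.242 TPM, a level of less than 3 reads on a 1-kb transcript, to 15.4 ± 1.01 TPM. The acute-phase gene Saa3 rose by 5.49 ± 0.10, the cytokine gene Il1a by 4.01 ± 0.19 and the gelatinase gene Mmp9 by 3.73 ± 0.05. The largest falls of named genes included those of the water channel gene Aqp5 (-2.15 ± 0.22), the fractalkine receptor gene Cx3cr1 (-1.73 ± 0.09) and the muscle actin gene Acta1 (-1.65 ± 0.25).

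Of the 27 tested secreted factors that act on macrophages, 18 rose and 2 fell with IL-33, and 19 rose and 3 fell when adjusted over the list alone (camera adjusted p = 3.7e-22). The monocyte chemokine genes Ccl2 (chromosome 11, 82035571 to 82037453) and Ccl7 (chromosome 11, 82045712 to 82047525) rose from 315 ± 14.9 to 2075 ± 95.3 TPM and from 656 ± 115 to 1914 ± 207 TPM. Il6 (chromosome 5, 30013114 to 30019981) rose from 46.5 ± 2.19 to 306 ± 31.7 TPM. The eosinophil chemokine gene Ccl11 (chromosome 11, 82057823 to 82062955) rose from 7.64 ± 1.47 to 55.0 ± 9.29 TPM and Csf2, the gene of GM-CSF (chromosome 11, 54247271 to 54249667), from 0.158 ± 0.273 to 7.44 ± 1.68 TPM. Csf1, the gene of the macrophage growth factor M-CSF (chromosome 3, 107741048 to 107760469), was at 476 ± 8.72 and 453 ± 5.42 TPM, a log2 difference of -0.07 ± 0.03 that was not called (adjusted p = 0.19). Among the 11 neutrophil factors 10 rose and 0 fell (6.4e-29). Among the 5 eosinophil and type 2 chemokines 2 rose, Ccl11 and Ccl7 (0.00072). Among the 19 IL-17 response genes 17 rose, 18 over the list alone (1.5e-44). Among the 24 NF-kB response genes 19 rose, 20 over the list alone (3.0e-27), with Zc3h12a at 2.33 ± 0.05, Sod2 at 1.75 ± 0.04 and Nfkbia at 1.20 ± 0.05. These lists share members. Of 17 STAT6 response genes 11 rose and 1 fell (5.4e-12), led by Serpina3g and by Arg1, the arginase gene, at 2.09 ± 0.05. Of the 9 receptor genes 6 rose (3.5e-05), the largest rise being that of the decoy receptor gene Il13ra2 at 1.75 ± 0.09, with Il1rap at 0.54 ± 0.09 and Il4ra at 0.18 ± 0.04.

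**Figure D2:**
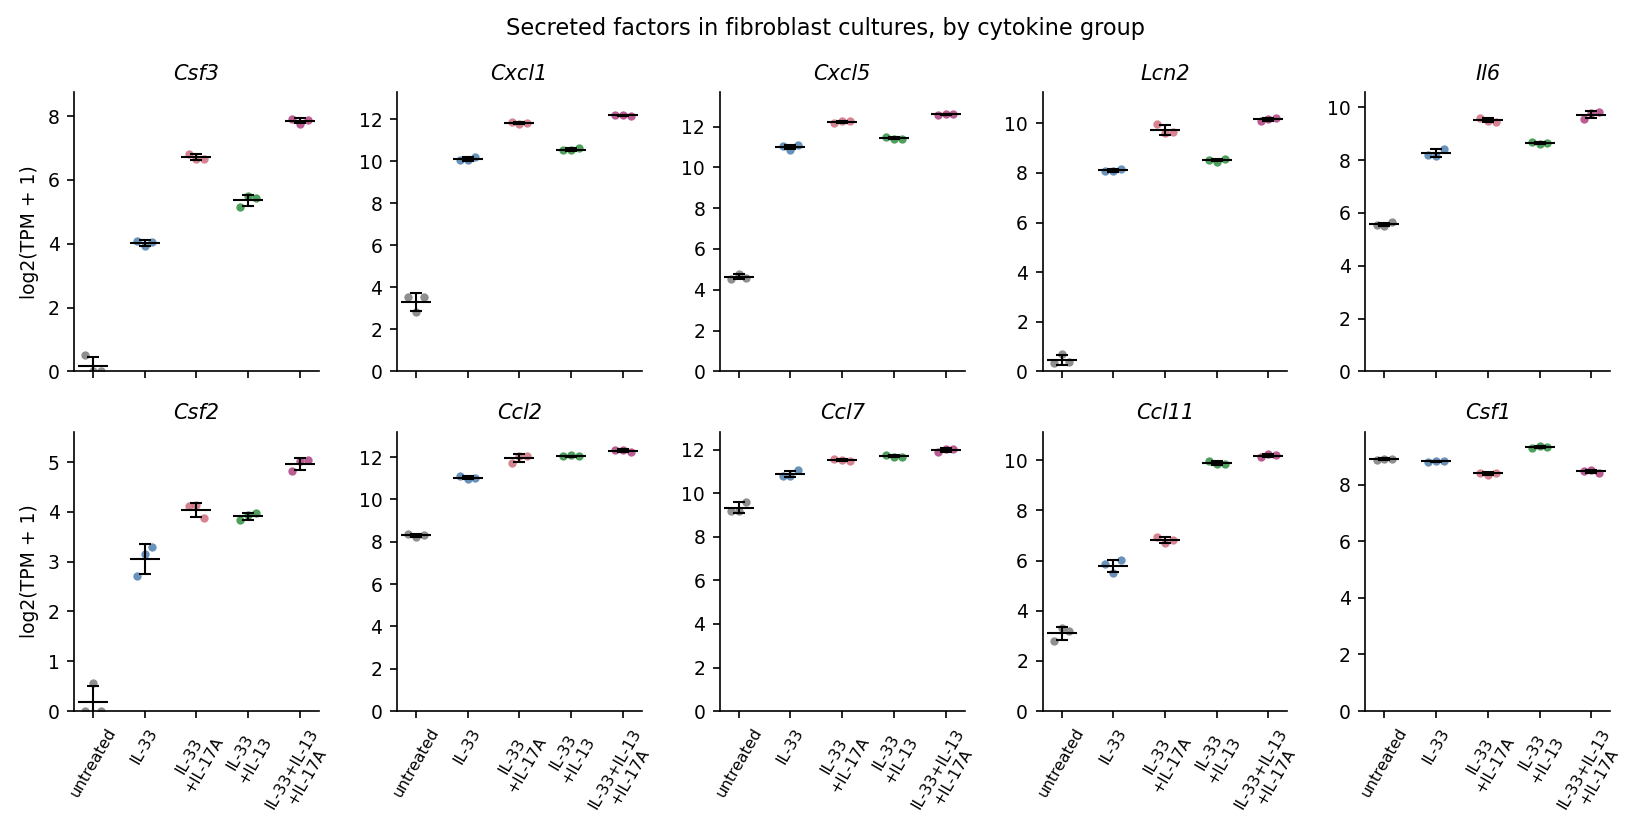
Expression of 10 secreted factors as log2(TPM + 1) in the 5 groups; each point is a library and each bar with whiskers the mean and SD of 3 libraries. Mean Csf3 is 0.140 TPM in untreated cells and 230.6 TPM in the triple combination, and mean Csf1 lies between 335 TPM with IL-33 and IL-17A and 637 TPM with IL-33 and IL-13.

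Of the 14 contractile and TGF-beta response genes 10 fell and 1 rose (camera adjusted p = 2.6e-05). Acta2, the smooth muscle actin gene used as a myofibroblast marker (chromosome 19, 34241090 to 34255590), fell from 1955 ± 39.1 to 1350.5 ± 11.1 TPM, -0.53 ± 0.04 on the log2 scale, and calponin, Cnn1, changed by -0.67 ± 0.04. Of the 6 smooth muscle and pericyte markers 5 fell (0.00011), among them Myh11 at -0.75 ± 0.06 and Mcam at -1.13 ± 0.12, and 3 of 6 mesothelial markers fell (0.031, adjusted p = 0.098 with an estimated correlation). Of 24 fibrillar collagen and matrix genes 13 fell and 4 rose (0.00054, adjusted p = 0.085 with an estimated correlation), with Col6a3 at -0.86 ± 0.04, the tenascin gene Tnc at 0.46 ± 0.03 and decorin, Dcn, at 0.97 ± 0.08. Col1a1 (chromosome 11, 94936224 to 94953042) was at 6107 ± 630 and 5201 ± 414 TPM and was not called (adjusted p = 0.16). Of 14 fibroblast markers 8 fell and 3 rose, with no list call (adjusted p = 0.16). Among 17 metalloproteinases and inhibitors 9 rose and 5 fell, 11 and 5 over the list alone (2.8e-06), with Mmp3 at 3.11 ± 0.07 and Mmp10 at 3.14 ± 0.09. Of 8 prostaglandin and eicosanoid enzymes 5 rose and 1 fell (8.5e-06): the prostaglandin E synthase gene Ptges rose by 1.63 ± 0.03 and the cyclooxygenase gene Ptgs2 by 1.24 ± 0.05, while Hpgd, whose product degrades prostaglandins, changed by -1.11 ± 0.12.

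Metabolic lists rose by small amounts with IL-33. Of 18 glycolysis and hypoxia genes 11 rose, 14 over the list alone (5.8e-13), with Vegfa at 0.64 ± 0.03 and Ldha at 0.28 ± 0.04. Of 16 cholesterol synthesis genes 8 rose, 14 over the list alone (3.0e-11). Of 28 cell cycle genes 8 rose and 2 fell, 11 and 2 over the list alone (6.5e-05, adjusted p = 0.16 with an estimated correlation). Of 12 complement genes 4 rose and 2 fell (0.0098, adjusted p = 0.16 with an estimated correlation), with Cfb at 2.47 ± 0.15 and C3 at 1.13 ± 0.06. Of 18 growth factors and morphogens 7 rose and 4 fell, 10 and 4 over the list alone (0.0026, adjusted p = 0.28 with an estimated correlation): Ereg, of the EGF family, rose by 1.58 ± 0.09 and Tgfb3 changed by -0.88 ± 0.04. Of 14 immediate early and heat shock genes 6 rose and 3 fell, 7 and 3 over the list alone (0.0024, adjusted p = 0.098 with an estimated correlation), with Ier3 at 1.52 ± 0.04. Of 25 interferon-stimulated genes 9 fell and 3 rose, 13 and 3 over the list alone (0.031, adjusted p = 0.42 with an estimated correlation), with Ifi44 at -0.92 ± 0.09 and, in the other direction, the guanylate-binding protein gene Gbp7 at 1.58 ± 0.12. The unfolded protein and amino acid stress list was not called (0.087) although 7 of its 18 members fell, 9 over the list alone, among them Atf3 at -0.84 ± 0.08 and Trib3 at -0.83 ± 0.10. No member of the 14 class I antigen presentation genes (0.81) or of the 13 mitochondrially encoded genes (0.41) was called. Class II genes (1 of 3 rose, 0.13), macrophage markers (3 rose and 2 fell of 13, 0.79), lymphocyte and ILC2 markers (1 rose and 1 fell of 3, 0.79) and endothelial markers (1 of 3 rose, 0.20) were not called as lists. Among the macrophage markers the mannose receptor gene Mrc1 rose by 0.65 ± 0.06 and Adgre1 changed by -0.21 ± 0.04. The mast cell and basophil, neutrophil and eosinophil, and epithelial lists had 2 tested members each and were not tested.

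Over all genes, 822 were higher and 1150 lower with IL-33 (1972 called by limma, 188 at a change of 2-fold or more, of which 136 were higher). None of the 6 libraries inside the set entered this comparison's groups. With median-ratio scaling of TPM, chosen after seeing the data, the split was 1079 higher and 887 lower, since the median log2 change of all genes moved from -0.05 to -0.01. Over the 9 comparisons these medians lay between -0.12, for IL-33 and IL-13 against untreated, and 0.06, for the interaction.

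IL-17A added to IL-33 raised the neutrophil factors further. Csf3 rose from 15.4 ± 1.01 to 104.6 ± 6.95 TPM (n = 3 in each group), a log2 change of 2.69 ± 0.13 (limma adjusted p = 6.0e-08). Nos2, the gene of the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), rose from 11.98 ± 0.47 to 128.7 ± 11.2 TPM, the largest change of a named gene at 3.32 ± 0.07 (2.7e-11). Lcn2 reached 858 ± 127 TPM, Cxcl1 3621 ± 91.7 TPM and Cxcl5 4825.5 ± 190 TPM. The largest falls of named genes included those of Ankrd1, a cardiac ankyrin repeat gene also expressed in mesenchymal cells (-1.86 ± 0.06, 5.4e-09), and Timp3, an inhibitor of metalloproteinases (chromosome 10, 86300372 to 86349506), which fell from 162 ± 5.75 to 54.0 ± 4.75 TPM (-1.57 ± 0.06, 9.4e-09).

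By list, 10 of 11 neutrophil factors rose (camera adjusted p = 1.9e-20), 15 of 19 IL-17 response genes, 16 over the list alone (1.2e-24), and 11 of 24 NF-kB response genes, 13 over the list alone (2.5e-16). Nfkbiz, a co-activator needed for many IL-17 target genes, rose by 1.66 ± 0.04 and Zc3h12a, which encodes the RNase Regnase-1, by 1.84 ± 0.05. Of the 27 secreted factors that act on macrophages 13 rose and 2 fell, 16 and 3 over the list alone (7.2e-13). Il6 rose to 732 ± 39.1 TPM (1.26 ± 0.08), Lif by 1.47 ± 0.07 and Ccl2 to 3970 ± 515 TPM (0.93 ± 0.08), whereas Csf1 fell from 453 ± 5.42 to 335 ± 8.68 TPM (-0.43 ± 0.03, 3.5e-06). Of 17 STAT6 response genes 7 rose and 2 fell (5.5e-06), with Il13ra2 at 0.93 ± 0.09, and of 5 eosinophil and type 2 chemokines 2 rose, 3 over the list alone (0.00026). Among 14 contractile genes 12 fell (1.4e-15), with Acta2 at -1.01 ± 0.04 and 672 ± 49.4 TPM and Cnn1 at -1.09 ± 0.04. Matrix genes fell in 15 of 24 cases and rose in 1, 19 and 3 over the list alone (7.1e-08), with Col6a3 at -0.71 ± 0.04, while Col1a1 was not called (-0.13 ± 0.10, adjusted p = 0.42). Smooth muscle and pericyte markers fell in 5 of 6 cases (1.3e-05). Prostaglandin enzymes rose in 4 of 8 (1.1e-06), with Ptgs2 at 0.89 ± 0.05, and cholesterol synthesis genes in 4 of 16, 5 over the list alone (5.5e-06). A further 6 lists were called and lost the call with an estimated correlation: receptors (0.047, then adjusted p = 0.27), interferon-stimulated genes (0.043, then 0.51), metalloproteinases and inhibitors (0.029, then 0.27), cell cycle genes (0.0015, then 0.28), glycolysis and hypoxia genes, 4 of which rose (0.0026, then 0.12) and mesothelial markers (0.050, then 0.14). The 4 cell cycle genes that fell were not called with the set term.

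IL-17A added to IL-33 changed 1355 genes over all, 491 higher and 864 lower, of which 84 changed at least 2-fold (63 of these were called with the set term). Of the 3 libraries with IL-17A, 2 lie inside the set with the lower mitochondrial share. With the set term 835 genes were called, 369 higher and 466 lower, 728 of them called with the same sign without it, and 316 were called in the 9 libraries outside the set. The compared groups alone gave 550 calls, median-ratio scaling 676 higher and 659 lower. Leaving out 1 library with IL-33 and IL-17A gave 3057 (replicate 1), 833 (replicate 2) or 810 (replicate 3), and leaving out IL-33 replicate 2 gave 881. Replicate 1 with IL-33 and IL-17A is the only library of its group outside the set, so without it the compared groups lie on opposite sides of the set.

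With IL-13 added to IL-33, Msx3 and Aldh1a3 rose most among named genes. Msx3, a homeobox gene (chromosome 7, 140046157 to 140049089), went from 0.234 TPM, under 3 reads on a 1-kb transcript, to 38.8 ± 3.21 TPM (SD, n = 3), a log2 change of 5.02 ± 0.15 (limma adjusted p = 5.4e-10). Aldh1a3, a retinaldehyde dehydrogenase gene (chromosome 7, 66390890 to 66427517), rose from 0.793 to 43.8 ± 1.52 TPM, a change of 4.66 ± 0.11. Ccl11 rose from 55.0 ± 9.29 to 944 ± 46.1 TPM (4.09 ± 0.13, 1.2e-09). The IL-33 receptor gene Il1rl1 (chromosome 1, 40429570 to 40465415) rose from 65.2 ± 8.23 to 336 ± 9 TPM (2.35 ± 0.08) and Il13ra2 (chromosome X, 147383476 to 147429192) from 2.91 ± 0.377 to 22.2 ± 1.06 TPM (2.58 ± 0.09). Among the largest falls were Dio3, a thyroid hormone deiodinase gene (-1.97 ± 0.17), Ccn5, of the CCN family (-1.74 ± 0.05), and Itga11, a collagen-binding integrin gene (-1.73 ± 0.07).

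Of 17 STAT6 response genes 14 rose and 1 fell (camera adjusted p = 1.4e-15), with the signalling inhibitor gene Cish at 2.81 ± 0.10 and Arg1 at 1.46 ± 0.05, and of 5 eosinophil and type 2 chemokines 4 rose (1.3e-05). Of 27 secreted factors that act on macrophages 15 rose and 6 fell, 15 and 7 over the list alone (5.3e-07). Ccl2 rose to 4220 ± 77.3 TPM (1.02 ± 0.08), Ccl7 to 3320 ± 107 TPM (0.80 ± 0.10), Csf3 to 40.2 ± 5.09 TPM (1.33 ± 0.13) and Csf1 to 637 ± 13.8 TPM (0.49 ± 0.03, 6.9e-07), the one combination in which Csf1 was above untreated cells. Of 11 neutrophil factors 9 rose (3.6e-07), with Cxcl3 at 2.41 ± 0.11, and of 19 IL-17 response genes 9 rose and 1 fell (2.6e-05), while the IL-17 receptor gene Il17ra changed by -0.57 ± 0.06. The receptor list was not called (0.17, adjusted p = 0.47 with an estimated correlation), but was with the set term and the preset correlation (0.011). NF-kB response genes, of which 7 rose and 8 fell, were not called (0.36), and with the set term 5 rose and 1 fell (0.11). Glycolysis and hypoxia genes (0.24) and fibroblast markers (0.13) were not called either, but were, downward, with the set term and the preset correlation (0.00029 and 0.035). With an estimated correlation, run without the set term, their adjusted p was 0.57 and 0.18. Cell cycle genes rose in 15 of 28 cases and fell in 0, 20 and 0 over the list alone (2.5e-11), with Rrm2 at 0.65 ± 0.05 and Cdc20 at 0.67 ± 0.06. Contractile genes fell in 13 of 14 cases (7.1e-09), with Acta2 at -0.85 ± 0.04 and 747 ± 13.5 TPM and Cnn1 at -0.94 ± 0.04. Smooth muscle and pericyte markers fell in 4 of 6, 5 over the list alone (0.0048). Of 24 matrix genes 14 fell and 2 rose, 17 and 2 over the list alone (7.6e-05, adjusted p = 0.063 with an estimated correlation), with Col6a3 at -1.23 ± 0.04. Col1a1 was at 4027 ± 78.5 TPM (-0.37 ± 0.10, 0.015); without IL-33 replicate 2 it was at -0.34 (adjusted p = 0.051) and with median-ratio scaling at -0.28 (0.099). Prostaglandin enzymes rose in 5 of 8 cases and fell in 1 (0.0012), with the prostacyclin synthase gene Ptgis at 1.22 ± 0.06.

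Interferon-stimulated genes fell in 16 of 25 cases when IL-13 was added to IL-33, 18 over the list alone (1.3e-05, adjusted p = 0.18 with an estimated correlation), with Ifi44 at -1.01 ± 0.09 and Gbp2 at -0.98 ± 0.07, and 4 of them fell with the set term. The 13 mitochondrially encoded genes, which define the library set, fell in 7 cases, 8 over the list alone (0.041, adjusted p = 0.59 with an estimated correlation), with mt-Nd1 at -0.43 ± 0.10, and in 0 cases with the set term (mt-Nd1 -0.11, adjusted p = 0.42). Unfolded protein response genes rose in 5 of 18 cases and fell in 4 (0.040, adjusted p = 0.10 with an estimated correlation), with the chaperone gene Hspa5 at 0.35 ± 0.03 and Pdia4 at 0.45 ± 0.05, and with the set term 6 rose and 1 fell. Cholesterol synthesis genes rose in 5 of 16 (0.035, adjusted p = 0.20 with an estimated correlation), and 1 of them with the set term. Of 13 macrophage markers 2 rose and 6 fell, and 2 and 2 with the set term, without a list call (0.60), with Mrc1 at 0.84 ± 0.06.

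**Figure D3:**
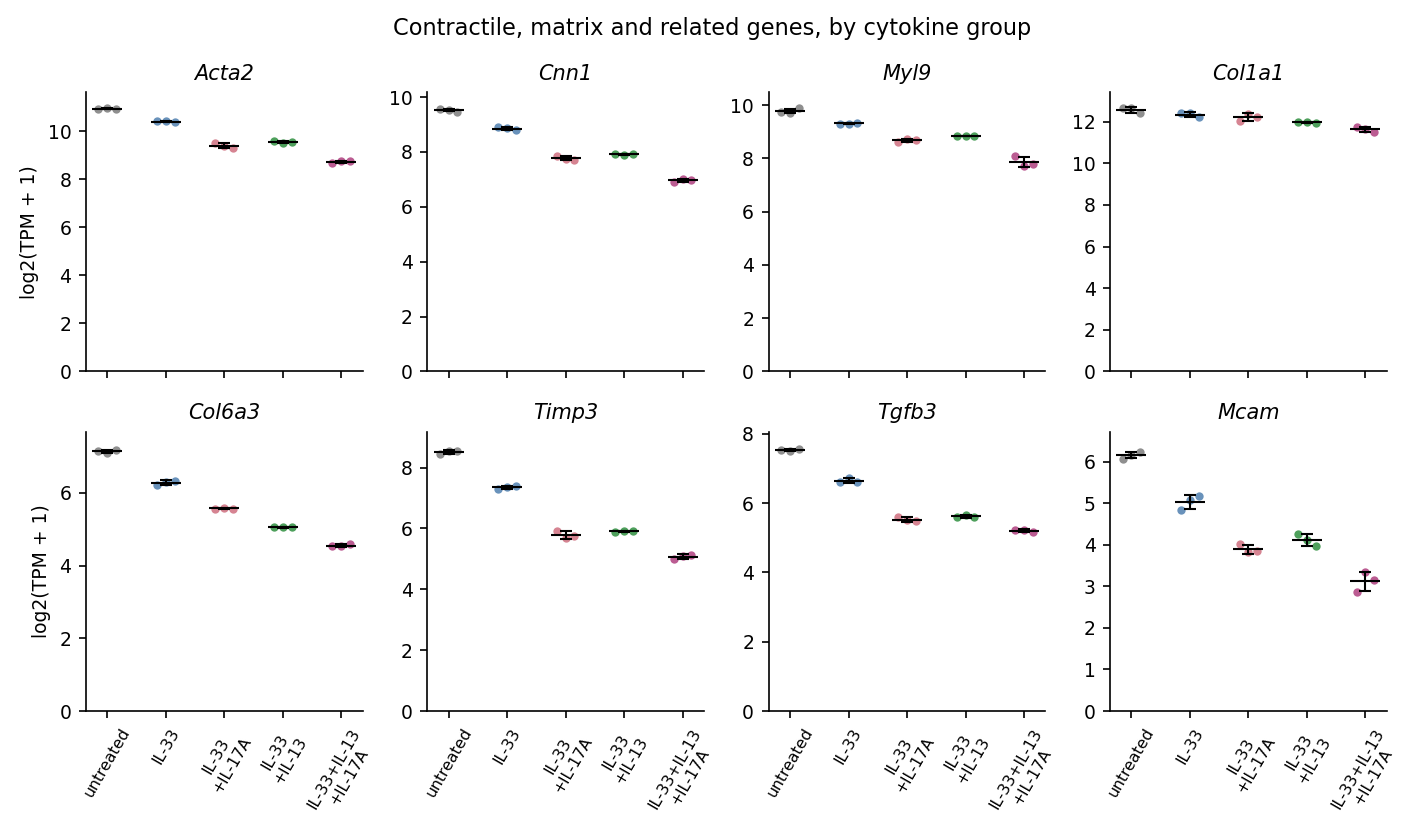
Expression of contractile, matrix and related genes as log2(TPM + 1) in the 5 groups; each point is a library and each bar with whiskers the mean and SD of 3 libraries. Mean Acta2 is 1955 TPM in untreated cells and 421 TPM in the triple combination, and mean Col1a1 is 6107 and 3189 TPM.

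IL-13 added to IL-33 changed 4506 genes over all, 1395 higher and 3111 lower, of which 218 changed at least 2-fold (135 of these were called with the set term). All 3 libraries with IL-13 lie inside the set and all 3 with IL-33 outside it. The set term therefore rests on the groups with libraries of both kinds, IL-33 with IL-17A and the triple combination. With the set term 1420 genes were called, 659 higher and 761 lower, and 1202 were called with the same sign in both. The share of higher genes was 31.0%, and 50.5% with median-ratio scaling (2204 higher and 2159 lower).

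IL-17A added to the combination of IL-33 and IL-13 again raised neutrophil factors and lowered contractile genes. Nos2 rose from 7.01 ± 0.511 to 101 ± 3.6 TPM (n = 3 in each group), a log2 change of 3.67 ± 0.07 (limma adjusted p = 8.0e-12), Csf3 from 40.2 ± 5.09 to 230.6 ± 13.2 TPM (2.50 ± 0.13, 2.1e-07) and the Notch ligand gene Dll1 by 2.40 ± 0.09. Il33, the gene of the alarmin given to the cells (chromosome 19, 29925114 to 29960718), rose from 17.6 ± 1.14 to 53.5 ± 5.89 TPM (1.54 ± 0.11). Csf1 fell from 637 ± 13.8 to 354 ± 13.5 TPM (-0.84 ± 0.03, 1.9e-08), the endothelin gene Edn1 changed by -1.37 ± 0.15 and Acta2 by -0.82 ± 0.04. Neutrophil factors rose in 9 of 11 cases (camera adjusted p = 3.2e-15), IL-17 response genes in 14 of 19 (5.1e-17), with Lcn2 at 1.64 ± 0.10 and Nfkbiz at 1.58 ± 0.04. Secreted factors that act on macrophages rose in 11 of 27, with 2 falls, 13 and 3 over the list alone (3.5e-06). Il6 rose by 1.07 ± 0.08, while Ccl2 was at 0.26 ± 0.08 (adjusted p = 0.066), Ccl7 at 0.30 ± 0.10 (0.10) and Ccl11 at 0.30 ± 0.13 (0.19). NF-kB response genes rose in 9 of 24 cases and fell in 1, 14 and 1 over the list alone (1.5e-07). Contractile genes fell in 12 of 14 cases and rose in 1 (7.6e-19), and smooth muscle and pericyte markers fell in 5 of 6 (4.2e-07). Matrix genes fell in 7 of 24 and rose in 1, 13 and 1 over the list alone (3.6e-05, adjusted p = 0.055 with an estimated correlation). Prostaglandin enzymes rose in 4 of 8 (0.00020) and cholesterol synthesis genes in 5 of 16, 2 with the set term, and 11 over the list alone with 1 fall (3.8e-05). Metalloproteinases and inhibitors (0.021, then adjusted p = 0.31 with an estimated correlation), growth factors (0.0032, then 0.33), cell cycle genes, with 4 falls (0.0030, then 0.33), and mitochondrially encoded genes, with 0 members called (0.015, then 0.48), were called with the preset correlation. The mitochondrial list, whose genes define the library set, was not called with the set term (adjusted p = 0.62), and its median log2 change went from 0.28 to 0.03.

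IL-17A changed 1034 genes here, 472 higher and 562 lower, or 592 and 576 with median-ratio scaling. With the set term 566 were called, with the 6 libraries inside the set, where the triple combination has 1 library, 210, and in a fit of the compared groups 590. Leaving out a library with IL-33 and IL-13 gave 593 (replicate 1), 493 (replicate 2) or 613 (replicate 3), and leaving out a library of the triple combination gave 1961 (replicate 1), 505 (replicate 2) or 516 (replicate 3). Replicate 1 of the triple combination is the only library of its group inside the set, so without it the compared groups lie on opposite sides of the set.

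IL-13 added to IL-33 and IL-17A raised Msx3 (4.64 ± 0.15, limma adjusted p = 1.1e-09, n = 3), Aldh1a3 (4.46 ± 0.11) and Ccl11, from 112 ± 9.95 to 1161 ± 47 TPM (3.36 ± 0.13, 8.8e-09). Csf3 rose by 1.13 ± 0.13 (1.14, adjusted p = 0.13, with a pseudocount of 0.1), Il13ra2 by 2.25 ± 0.09 and Il1rl1 by 2.11 ± 0.08, and Ccn5 (-2.01 ± 0.05), Dio3 (-1.78 ± 0.17) and Tnf (-1.62 ± 0.19) fell. Csf1, at 335 ± 8.68 and 354 ± 13.5 TPM, was not called (0.08 ± 0.03, adjusted p = 0.13). STAT6 response genes rose in 13 of 17 cases and fell in 1, 14 and 1 over the list alone (camera adjusted p = 5.6e-17), and cell cycle genes rose in 23 of 28, 27 over the list alone (5.5e-17). Neutrophil factors rose in 7 of 11 with 1 fall, 10 and 1 over the list alone (3.3e-06), and eosinophil and type 2 chemokines in 3 of 5, 4 over the list alone (6.2e-05). Secreted factors that act on macrophages rose in 12 of 27 with 6 falls, 15 and 7 over the list alone (0.00054). Unfolded protein response genes rose in 6 of 18 (0.0017), with Hspa5 at 0.40 ± 0.03, and prostaglandin enzymes in 4 of 8 with 1 fall (0.0012). Contractile genes fell in 11 of 14 cases (7.6e-14), with Acta2 at -0.67 ± 0.04, glycolysis and hypoxia genes in 10 of 18 (6.3e-06), with Pfkfb3 at -0.37 ± 0.05, and smooth muscle and pericyte markers in 3 of 6 (0.00075). The following calls were lost with an estimated correlation: interferon-stimulated genes, 10 of which fell (1.7e-05, then adjusted p = 0.14), class I antigen presentation, 5 falls (0.0060, then 0.089), and matrix, 11 falls and 2 rises (0.00068, then 0.089). So were those of complement, 6 falls and 2 rises (0.020, then 0.20), cholesterol synthesis, 2 rises (0.0060, then 0.093), IL-17 response genes, 6 rises and 3 falls (0.026, then 0.16), and mesothelial markers, 3 rises (0.024, then 0.089).

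IL-13 changed 2199 genes in this setting, 930 higher and 1269 lower, and with the set term 2448, of which 1993 were called with the same sign in both. Median-ratio scaling gave 1181 higher and 1167 lower. The 9 libraries outside the set gave 824 calls, the 6 inside 644, the compared groups alone 803, and leaving out replicate 2 of the triple combination 1451.

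The interaction asks whether IL-17A acted differently with IL-13 present. It was called for 47 genes, 22 higher and 25 lower. Tgfb3, a TGF-beta gene (chromosome 12, 86056745 to 86079041), changed by -1.12 with IL-17A on IL-33 alone and by -0.41 with IL-13 present, a difference of 0.72 ± 0.06 (limma adjusted p = 0.00027). Rgs16, a regulator of G protein signalling (chromosome 1, 153740349 to 153745468), changed by 0.86 and by 0.19 (difference -0.67 ± 0.05, 0.00026), with 246 ± 3.37, 448 ± 11.7, 516 ± 14.4 and 589.5 ± 16.9 TPM in the 4 groups with IL-33. Csf1 changed by -0.43 and by -0.84 (difference -0.41 ± 0.05, 0.0029), Lif by 1.47 and 0.69 (-0.78 ± 0.09, 0.0032), Cish by 1.08 and 0.02 (-1.07 ± 0.14, 0.0071) and Timp3 by -1.57 and -0.82 (0.75 ± 0.08, 0.0029). Csf3 was not called (-0.19 ± 0.18, adjusted p = 0.51). Of 27 secreted factors that act on macrophages 3 had a negative interaction (camera adjusted p = 0.0077, adjusted p = 0.062 with an estimated correlation).

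Of the 47 genes, Rgs16 (-0.66, 0.026) and Tgfb3 (0.66, 0.030) were called with the set term. All 47 kept their sign, but they were chosen in these same libraries. Median-ratio scaling gave 95 calls and removal of the GC trend 127, and leaving out 1 library gave between 21 and 3038. There were 3038 without IL-33 and IL-17A replicate 1, the only library of its group outside the set. There were 2284 without replicate 1 of the triple combination, the only library of its group inside it. Without either, its group lies wholly on 1 side, so the set cannot be told apart from the interaction in these calls. There were 31, 21 and 30 without IL-33 replicates 1, 2 and 3, 22 and 25 without IL-33 and IL-17A replicates 2 and 3, 23, 23 and 27 without IL-33 and IL-13 replicates 1, 2 and 3, and 21 and 23 without replicates 2 and 3 of the triple combination. Across the 1889 genes called for IL-17A in either setting the 2 effects, which share no library, had a Pearson correlation of 0.45 and the same sign in 74.3%, against 0.65 and 92.6% over 998 genes with the set term and 0.055 and 44.7% over all tested genes. For IL-13 without and with IL-17A the correlation was 0.56 over 5343 genes, with the same sign in 75.1%. It was 0.77 over 2745 genes with the set term (same sign in 93.4%) and 0.34 over all tested genes (59.5%). Genes are not replicates here and no p is given.

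**Figure D4:**
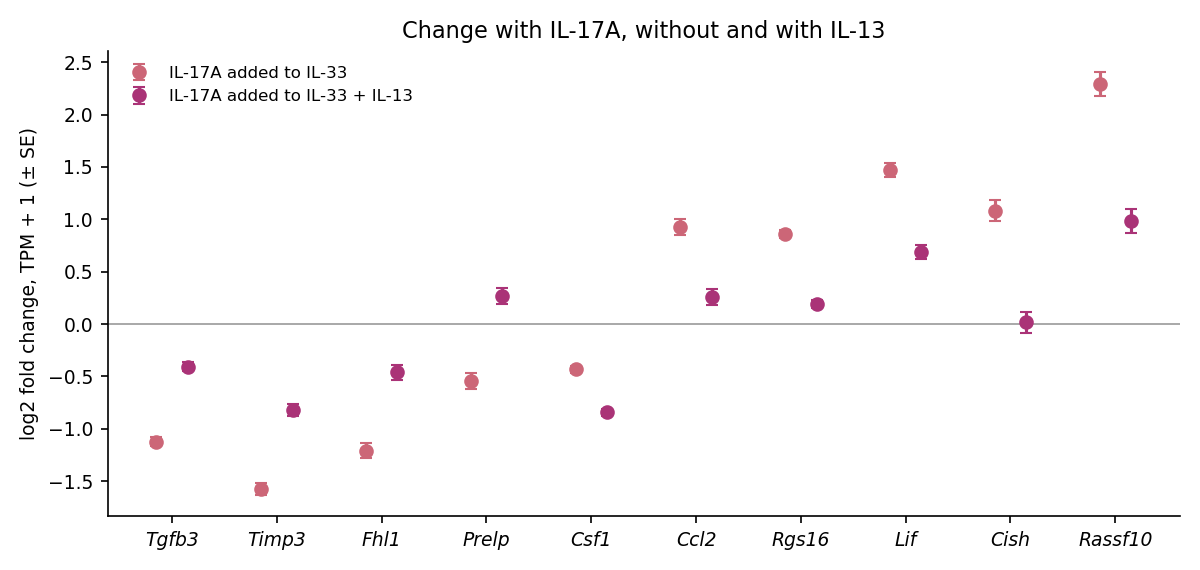
Log2 change with IL-17A when IL-13 was absent and when it was present, on top of IL-33, for 10 genes called for the interaction; points are limma estimates from 3 libraries per group and bars 1 SE. Tgfb3 is at -1.12 and -0.41, Csf1 at -0.43 and -0.84, and Rgs16 at 0.86 and 0.19.

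Against untreated cells, 743 genes changed at least 2-fold with the triple combination, 568 with IL-33 and IL-13 and 502 with IL-33 and IL-17A. Lcn2 was at 1147 ± 49.3 TPM against 0.398 ± 0.198 (log2 change 9.69 ± 0.10, limma adjusted p = 4.1e-15, n = 3), Cxcl1 at 8.88 ± 0.15, Cxcl5 at 7.96 ± 0.07, Csf3 at 7.69 ± 0.13 and Ccl11 at 7.09 ± 0.13. Csf2 reached 30.3 ± 2.5 TPM (4.78 ± 0.16), Ccl2 5053 ± 214 TPM (3.998 ± 0.077), Ccl7 4092 ± 226 TPM (2.65 ± 0.10) and Il6 846 ± 77.5 TPM (4.15 ± 0.08), while Csf1 was lower than in untreated cells (-0.43 ± 0.03). Timp3 (-3.43 ± 0.06), Ccn5 (-3.09 ± 0.05), Mcam (-3.04 ± 0.12), Col6a3 (-2.60 ± 0.04) and Acta2 (-2.21 ± 0.04) fell, and Col1a1 fell to 3189 ± 251 TPM (-0.93 ± 0.10). Of 27 secreted factors that act on macrophages 21 rose and 4 fell (camera adjusted p = 4.0e-15), of 11 neutrophil factors 11 rose (8.4e-20), and of 19 IL-17 response genes 18 (4.0e-27). Of 17 STAT6 response genes 15 rose (1.8e-16), of 24 NF-kB response genes 19, with 1 fall (3.3e-15), and of 16 cholesterol synthesis genes 13 (1.8e-11). Contractile genes fell in 12 of 14 cases (9.1e-10), matrix genes in 20 of 24 with 4 rises (3.4e-06) and smooth muscle and pericyte markers in 5 of 6 (0.00011). Interferon-stimulated genes fell in 20 of 25 with 2 rises (3.4e-05, adjusted p = 0.16 with an estimated correlation) and cell cycle genes rose in 17 of 28 (4.2e-09, adjusted p = 0.059 with an estimated correlation). Of 13 macrophage markers 3 rose and 7 fell, without a list call (0.90).

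With IL-33 and IL-17A the largest changes from untreated cells included those of Lcn2 (9.26 ± 0.10), Cxcl1 (8.52 ± 0.15) and Nos2 (6.89 ± 0.07) and, downward, Acta1 (-3.04 ± 0.25) and Timp3 (-2.73 ± 0.06). With IL-33 and IL-13 they included those of Lcn2 (8.05 ± 0.10), Ccl11 (6.79 ± 0.13) and, downward, Acta1 (-2.73 ± 0.25) and Aspn (-2.64 ± 0.15), with limma adjusted p between 1.8e-15 for Nos2 in the first and 3.1e-06 for Acta1 in the second. Csf1 was lower in the first (-0.51 ± 0.03) and higher in the second (0.42 ± 0.03). Secreted factors that act on macrophages rose in 21 of 27 cases in both, with 4 and 5 falls (camera adjusted p = 5.3e-18 and 8.1e-16). Over all genes 5933 differed from untreated in the triple combination (1755 higher), 5229 with IL-33 and IL-17A (1486 higher) and 6887 with IL-33 and IL-13 (2017 higher), and 5964, 3452 and 3549 with the set term. The 9 libraries outside the set, with 1 of IL-33 and IL-17A, gave 2152 for that combination. With median-ratio scaling the counts of higher and lower genes were 2687 and 2702, 2324 and 2347, and 3195 and 3180. Over all 9 comparisons the preset correlation gave 142 list calls and the estimated correlation 87, all among the 142.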

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

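The tests on the library set other than that of GC content, the test on macrophage transcripts and that on the set's share in the interaction, were chosen after the result was seen; the GC test and the counts of other splits were written before.

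A test of the difference itself picked out the interaction of IL-13 and IL-17A, in which 47 genes were called, without a term for the library set, for a difference of the IL-17A effect without and with IL-13. Named genes with a positive interaction were Tgfb2 (0.89), Rc3h2 (0.86), Prelp (0.81), Timp3 (0.75), Fhl1 (0.75) and Tgfb3 (0.72), and those with a negative one were Rassf10 (-1.305), Cish (-1.07), Lif (-0.78), Rgs16 (-0.67), Ccl2 (-0.67), Arg1 (-0.46), Zc3h12a (-0.45), Csf1 (-0.41) and Ptges (-0.27). Of these, 5 lost the call when 1 library was left out. Arg1 lost it without IL-33 replicate 2 (-0.445, adjusted p = 0.055), IL-33 and IL-13 replicates 1 (0.058) and 2 (0.056) and replicate 2 of the triple combination (0.061), and Rc3h2 without IL-33 replicate 2 (0.86, 0.055), IL-33 and IL-13 replicate 2 (0.056) and replicates 2 (0.065) and 3 (0.057) of the triple combination. Ccl2 (adjusted p of 0.060 to 0.083) and Ptges (0.055 to 0.11) lost it without IL-33 replicates 2 or 3, IL-33 and IL-17A replicates 2 or 3, any library with IL-33 and IL-13, or replicates 2 or 3 of the triple combination. Zc3h12a lost it without any library of the 4 groups except replicate 1 with IL-33 and IL-17A and replicate 1 of the triple combination (0.054 to 0.093). Rassf10, a low gene, lost it with a pseudocount of 0.1 (-1.92, 0.095).

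The same test picked out 6 lists by camera: secreted factors that act on macrophages (adjusted p = 0.0077, and 0.062 with an estimated correlation), IL-17 response genes (0.0107, 0.21), STAT6 response genes (0.0152, 0.13), NF-kB response genes (0.0107, 0.42) and class I antigen presentation (0.0153, 0.21), all downward, and mitochondrially encoded genes (0.0107, 0.59), upward. With the set term and the preset correlation camera called 9 lists: the first 4 of these, receptors (0.0027), neutrophil factors (0.011), prostaglandin enzymes and complement (0.044 each), all downward, and matrix (0.044), upward. With an estimated correlation, run without the set term, the 5 added lists had an adjusted p of 0.73, 0.21, 0.55, 0.69 and 0.59. Class I antigen presentation (0.37) and the mitochondrial list (0.97) were not among them.

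The interaction weighs the library set heavily, since 2 of 3 libraries with IL-33 and IL-17A, 3 of 3 with IL-33 and IL-13 and 1 of 3 of the triple combination lie inside it. For the 47 genes the median ratio of the interaction with the set term to that without was 0.745 (0.495 to 1.08), the median size went from 0.61 to 0.44 and the median SE from 0.090 to 0.102, so on the median a smaller change and a larger error went with the lost calls, and a part played by the set cannot be told apart from an interaction. Csf1 differs from that median, as it went from -0.41 to -0.44. It lost the call (adjusted p = 0.073) with a larger error (SE 0.047, then 0.063). All 47 genes stayed at an unadjusted p under 0.05, but they were chosen by their interaction in these same libraries, so this is no separate support. Over all 13887 tested genes, 657 had an unadjusted limma p under 0.05 with the set term, against 3750 without it. Of 100 regroupings of the 12 libraries with IL-33, 3 gave 47 calls or more, the real one included, a share under 0.05. The highest other gave 624 and sets the 6 libraries with IL-17A against the 6 without, a structure of the samples. The remaining regrouping gave 221 calls, is balanced over the set and weighs IL-13 more than IL-17A. Since regroupings mix cytokine conditions, which widens their spread, the share cannot decide on chance. The 8 other regroupings that weigh the set as the real one does gave 0 to 37 calls by limma, fewer than 47, which runs against the set alone, but regroupings mix cytokine conditions, which widens their spread, so a part played by the set stays open.

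The term for the 6 libraries with a low mitochondrial share was called for 2262 genes. It rests on the 2 groups with libraries on both sides, IL-33 with IL-17A and the triple combination, each with 1 library on 1 side. The cytokines as the whole cause are argued against, because in these 2 groups libraries given the same cytokines lie on both sides. The smallest gap between a library inside and one outside the set was 1.15 percentage points within the triple combination and 1.57 within IL-33 and IL-17A. As the set was cut at the widest gap in mitochondrial TPM, a small gap could not occur, so its size adds nothing. After removal of each library's GC trend 1135 genes were called for the set, a number that is 50.2% of that before. Of these, 892 were called with the same sign in both fits, so the 1135 are not simply what was left of the 2262. The share lies just past the bound against GC content that was written before. A 95% Clopper-Pearson interval of 48.1% to 52.3% spans that bound, but it was not in the rule and treats genes as independent. GC content stays open as a part of what sets these libraries apart. A different mix of macrophages and fibroblasts also stays open, as the median set coefficients of their markers differed by 0.039, and the shift between the lists had a 95% interval of -0.13 to 0.12 (Wilcoxon). The 6 libraries are consecutive in accession order, so a difference in handling stays open too, untested, as the labels give no batch, date or animal.

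Macrophage transcripts were present in all 15 libraries. No test of macrophages in the cultures was run that is separate from these transcripts, so that explanation stays open. The larger of the median levels of epithelial and endothelial markers was 0.157% of that of macrophage markers. Of the epithelial and endothelial markers 0 averaged 10 TPM or more, against 13 macrophage markers. This argues against leftover epithelium and endothelium as abundant as macrophages. The ratio compares different genes scaled by gene span, so it is no share of cells. Markers of other leftover cells, such as mast cells, neutrophils and lymphocytes, were not part of it, so those stay open. The design gives no group that would separate genes read from fibroblasts from genes read from macrophages, so a change of a secreted factor here cannot be assigned to either cell.

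The 6 libraries of each of the other 8 comparisons can be split in 10 ways, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many genes. The real values and the highest of the other splits were 1972 and 1 for IL-33, 1355 and 1 for IL-17A added to IL-33, 4506 and 1 for IL-13 added to IL-33, 1034 and 1 for IL-17A added to IL-33 and IL-13, 2199 and 1816 for IL-13 added to IL-33 and IL-17A, and 5229 and 2, 6887 and 0, and 5933 and 1 for IL-33 with IL-17A, IL-33 with IL-13 and the triple combination against untreated. The split with 1816 genes follows the library set, and with the set term the real grouping gave 2448. For IL-13 added to IL-33 and for IL-33 with IL-13 against untreated the real split is itself that of the set.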

How the results depend on the processing

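The set term, the fits inside and outside the set, median-ratio scaling, GC trend removal, the set term in camera and the averaging of untreated replicates 1 and 2 were chosen after seeing the data. The counts for IL-33 against untreated (1426 to 1862 with 1 library left out) and the triple combination against untreated (5025 to 5614) stayed within 1.5 times under the settings run. With only the compared groups in the fit 550 genes were called for IL-17A added to IL-33, 590 for IL-17A added to IL-33 and IL-13 and 803 for IL-13 added to IL-33 and IL-17A, a fit with fewer libraries. With the set term the counts were 835 for IL-17A and 1420 for IL-13 added to IL-33, 566 for IL-17A added to IL-33 and IL-13, 2 for the interaction, and 3452 and 3549 for IL-33 with IL-17A and with IL-13 against untreated. The 9 libraries outside the set gave 316 for IL-17A added to IL-33, 824 for IL-13 added to IL-33 and IL-17A and 2152 for IL-33 with IL-17A against untreated, and the 6 inside 210 and 644 for IL-17A and IL-13 added to the other combination, with fewer libraries in each. Groups with 1 library there are assumed to vary like the others. The interaction gave 95 calls with median-ratio scaling and 127 after GC trend removal; the cause was not tested. Leaving out 1 library gave 810 (IL-33 and IL-17A replicate 3) to 3057 (its replicate 1) for IL-17A added to IL-33, 493 (IL-33 and IL-13 replicate 2) to 1961 (replicate 1 of the triple combination) for IL-17A added to IL-33 and IL-13, 1451 (replicate 2 of the triple combination) to 2542 (its replicate 1) for IL-13 added to IL-33 and IL-17A, and 21 (IL-33 replicate 2) to 3038 (IL-33 and IL-17A replicate 1) for the interaction. Replicate 1 with IL-33 and IL-17A is the only library of its group outside the set, and replicate 1 of the triple combination the only library of its group inside. Without either, its group lies wholly on 1 side, so a part played by the set in these highest counts cannot be told apart. List calls went from 142 to 87 with the estimated correlation. The correlation of the IL-17A effects went from 0.45 to 0.055 over all genes, most of which were not called, and 0.65 with the set term. The set enters these effects in opposite directions, as adding IL-17A goes with more libraries of the set without IL-13 and fewer with it. The cause of the drop was not tested. Signs turned for H2-K1 with IL-13 added to IL-33 (0.12 with the set term, adjusted p = 0.59), Il1rap there (0.16 after GC trend removal, 0.021), Il7r with IL-33 and IL-17A against untreated (0.22 after GC trend removal, 0.042), Il13ra1 with IL-33 and IL-13 against untreated (0.25 after GC trend removal, 0.00050) and H2-D1 in the triple combination against untreated (0.026 with median-ratio scaling, 0.68, and 0.0019 after GC trend removal, 0.97); the cause was not tested. Of the values of single named genes, 1023 kept direction and side of the threshold with the set term and 87 lost the call, against 1110 and 13 with a pseudocount of 0.1, 1115 and 6 without the filter, 1037 and 57 with the compared groups alone, 542 and 72 outside and 175 and 64 inside the set, 1086 and 25 with median-ratio scaling, 1073 and 22 after GC trend removal, 473 and 14 with averaged untreated replicates, and 7009 and 288 with 1 library left out. A second count test and other size factors were not run, since they need counts. No paired analysis was possible because the labels give no replicate numbers, and numbers in accession order do not pair libraries. Depth limits values under about 3 TPM to a few reads in genes that span about 1 kb, and less so in longer genes. Csf3 and Csf2 in untreated cells rest on a few reads at most.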

Other observations

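The values in this part were chosen after they were seen, and no test of an explanation was run on them. The alarmin and cytokine genes Il33, Tslp and Il11 were higher in each condition with more cytokines. Il33 averaged 4.45 ± 0.186 TPM in untreated cells, 11.1 ± 1.04 with IL-33, 25.1 ± 4.32 with IL-33 and IL-17A, 17.6 ± 1.14 with IL-33 and IL-13 and 53.5 ± 5.89 in the triple combination (SD, n = 3), and its log2 change from untreated to the last was 3.32 ± 0.11 (SE, limma adjusted p = 1.4e-10). Tslp, an epithelial alarmin gene, changed by 3.10 ± 0.12 between the same groups and Il11, a cytokine gene of the IL-6 family, from 35.3 ± 1.12 to 252 ± 17.9 TPM. Tnf was at 18.2 ± 3.71 TPM in untreated cells, 18.1 ± 2.9 with IL-33 and 19.6 ± 0.394 with IL-33 and IL-17A, and lower with IL-13, at 7.03 ± 0.196 TPM (-1.24 ± 0.19 on IL-33, adjusted p = 0.00051) and 5.89 ± 1.94 TPM in the triple combination. Dll1 was at 12.3 ± 0.53 and 9.39 ± 0.172 TPM in the 2 conditions with IL-17A, and at 0.598 ± 0.103, 2.27 ± 0.389 and 0.969 ± 0.181 TPM in untreated cells, with IL-33 and with IL-33 and IL-13.

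Transcripts typical of macrophages stayed abundant in each group. Cd68, a lysosomal gene, averaged 2267 TPM over the 15 libraries, Spp1, the osteopontin gene, 7500 TPM, and the complement genes C1qa and C1qc 2018 and 1732 TPM. Csf1r, the gene of the M-CSF receptor, was at 262 ± 8.79 TPM in untreated cells and 192 ± 11.2 TPM in the triple combination, and Mrc1 at 51.4 ± 2.34 and 154 ± 10.5 TPM. Cx3cr1 went from 5.03 ± 0.238 TPM to 0.816 ± 0.0124 TPM with IL-33 and 0.0818 ± 0.0323 TPM in the triple combination.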
